A study of Mus musculus with 3 samples.

How the data were processed

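Barcoded lung tumours were measured in 17 mice of 3 genotypes, given as 1 deposited table per genotype that keeps the mice apart. Per the labels' protocols, a lentiviral pool was delivered into the trachea, genomic DNA was taken from bulk tumour-bearing lung, 3 benchmark cell lines of 500000 cells each were added to every lung before lysis, and the guide and barcode region was amplified by PCR and sequenced. The deposited values are numbers of neoplastic cells per guide, barcode and mouse, per the file headers, and per the labels' protocols the authors computed cell numbers from barcode reads with the benchmark lines. The read trimming, the barcode clustering tool and their versions are not given in the sources used here. No genome build is involved, and no coordinates are given. The 4 gene symbols were found unchanged (4 of 4) in a table of mouse RefSeq genes. The benchmark lines' own reads were not used here.

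Within each mouse, all values (100%) were whole multiples, within a tolerance of 0.1, of the smallest value divided by 2, and 37.9% to 49.9% of them were odd multiples, so this step was taken as the worth of 1 read. The smallest multiple was 2, so barcodes seen once are not listed. Reads per mouse were recovered from this step. PCR reads without molecular identifiers are not independent molecules, and reads limit the precision of small tumours most in KPTC mouse 1, where 500 cells are 3.80 reads. The 2 KPTC mice numbered 3 and 4 are written with more digits than the other mice, which points to a separate processing run, and they were tested apart from mice 1 and 2. Mice were numbered in the order of their identifiers within a genotype, and the numbers pair no mice.

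Tumours of at least 500 cells were kept. Size was the maximum-likelihood mean of a log-normal distribution, number the count of tumours and burden the sum of cells, each as log2 of the gene over all inert guides in the same mouse, and the 50th, 60th, 70th, 80th, 90th, 95th and 99th percentiles were treated likewise. The mouse was the replicate. KTC and KPTC were each compared with KT, and with each other, by two-sided exact permutation tests of mouse labels over all splits, where the smallest p is 0.0014 for 9 against 4 mice and 0.029 for 4 against 4. Ambra1 was compared with each other gene by two-sided exact sign-flip tests within mice (smallest p 0.0039 for 9 mice and 0.125 for 4). Benjamini-Hochberg adjustment ran over the 4 genes (8 guides, 5 inert guides, 3 genotype pairs or 3 other genes) within a measure, with a threshold of 0.05. No count model across genes was used, since barcodes are labels of tumours and not features measured in every mouse, even where the same barcode occurs in several mice. Comparisons that share the KT mice also share their chance values. The rule for named genes took every targeted gene and every guide of the pool, with no selection.

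The tests were tried on simulated data, 100 draws per setting, in which inert tumours of the real mice stood in for a gene of known effect. With no effect, 0% to 6% of draws gave p under 0.05. A 4-fold enlargement of the tumours above 500 cells was recovered as a log2 size difference of 1.99 in KTC and 2.00 in KPTC. When every listed barcode was enlarged 4-fold, the size measure gave 0.10 and -0.09 and the number measure 2.82 and 2.18, because small tumours then pass the minimum. KPTC mouse 1 lists no barcode under 263 cells, so smaller tumours could not be lifted there. With every listed barcode enlarged 4-fold, number-matched size gave 1.99 and 1.98. A number excess predicted from number-matched size then differed from the simulated one by -0.0037 and 0.035, and by -2.82 and -2.20 when only tumours above 500 cells were enlarged. Predicted from size above 500 cells, which is too low a factor for a uniform shift, the excess was exceeded by 2.67 and 2.32 when every barcode was enlarged. Size above a fixed minimum therefore understates an enlargement that reaches small tumours too, and the number-matched values are given beside it.

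Alternatives fixed before the data were examined were minimum sizes of 200, 1000 and 5000 cells, each mouse left out in turn, barcodes 1 mismatch from a barcode at least 50 times larger left out, shared barcodes kept only in the mouse where they are largest, the geometric mean and the 95th percentile as size, number-matched largest tumours, exact sign-flip tests within a genotype, tumours pooled over mice with a bootstrap of 1000 draws and 95% intervals, each guide alone, each inert guide left out, and burden without the largest tumour. Alternatives chosen after seeing the data were a minimum of 10 reads, male mice only, barcodes listed in 1 mouse only, KPTC mice 1 and 2 or 3 and 4 only, KPTC mouse 1 left out at 200 cells and over all listed barcodes, and permutation within sex. All computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.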

Results

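Lung tumours were started in 17 mice with a pool of lentiviral vectors, each carrying Cre recombinase, 1 guide RNA and a random barcode, so that every tumour could be counted and sized by sequencing its barcode (tumour barcoding with deep sequencing, Tuba-seq). The pool held 13 guides. Of these, 8 targeted 4 genes, namely Ambra1 (3 guides), Rb1 (2 guides), Apc (1 guide) and Rbm10 (2 guides), and 5 were inert (NT1 and NT2, Neo1, Neo2 and Neo3), meaning that they cut no gene of the mouse genome that matters for growth. By the usage of this field, P in the genotype names stands for p53 deleted by Cre and C for Cas9. The 3 genotypes were KT, without Cas9 (4 mice, 2 female and 2 male), KTC, with Cas9 and wild-type p53 (9 mice, 5 female and 4 male), and KPTC, with Cas9 and without p53 (4 mice, all male). Lungs were taken about 15 weeks after tumour initiation. Since guides act only where Cas9 is present, KT mice were taken as the baseline for each guide's share of the virus.

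In all, 57536 tumours of at least 500 neoplastic cells were analysed, from 117 (KTC mouse 6) to 13332 (KT mouse 1) per mouse. Barcode reads per mouse ran from 338871 to 10456647. The worth of 1 read ran from 1.08 cells in KT mouse 4 to 132 cells in KPTC mouse 1, so that a tumour of 500 cells rested on 465 reads in the former and on 3.80 reads in the latter. Each mouse was 1 replicate. For every gene, the size, number and summed cells (burden) of its tumours were set against those of all inert tumours in the same mouse, as a log2 ratio. The ratios were compared with KT mice by two-sided exact permutation tests of mouse labels, with Benjamini-Hochberg adjustment over the 4 genes.

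The first comparison asked whether tumours grew larger when each gene was targeted in mice with wild-type p53. In KTC mice, tumours carrying Ambra1 guides were the largest of the pool. Ambra1 encodes a substrate adaptor of a cullin-RING ubiquitin ligase and is tied to the turnover of D-type cyclins. Ambra1 tumours had a log-normal mean size of 4434 ± 2005 cells (SD, n = 9 mice) beside 1350 ± 325 cells (SD, n = 9) for inert tumours, whereas in KT mice Ambra1 tumours had 1469 ± 201 cells and inert tumours 1591 ± 228 cells (SD, n = 4 each). The log2 ratio to inert tumours was 1.62 ± 0.43 (SD, n = 9) in KTC and -0.11 ± 0.07 (SD, n = 4) in KT, a 3.32-fold difference that held in 9 of 9 KTC mice, each above every KT mouse (exact permutation, adjusted p = 0.0028).

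The other targeted genes gave smaller increases in KTC mice. Tumours with the guide against Apc, a negative regulator of Wnt signalling, were 1.66-fold larger relative to KT (log2 ratio 0.86 ± 0.32, SD, n = 9, exact permutation, adjusted p = 0.0028). Tumours with guides against Rb1, which encodes the retinoblastoma protein that restrains entry into S phase, were 1.42-fold larger (0.52 ± 0.25, SD, n = 9, exact permutation, adjusted p = 0.0056). Both held in 9 of 9 mice. Tumours with guides against Rbm10, an RNA-binding regulator of splicing, were 1.38-fold larger (0.44 ± 0.36, SD, n = 9, exact permutation, adjusted p = 0.032), with 7 of 9 mice above every KT mouse. The Rbm10 call ended when any 1 of the 4 KT mice was left out (exact permutation, adjusted p 0.082 to 0.091). The log2 difference stayed at 0.44 to 0.47 there, beside 0.46 with all mice. The call also ended at a minimum of 1000 cells (log2 difference 0.35, exact permutation, adjusted p = 0.19), where KTC mouse 6 had few inert tumours left. The size of the increases also depended on which tumours entered: taking for each gene as many of its largest tumours as the KT ratio predicts raised them to 6.66-fold for Ambra1, 2.44-fold for Apc, 1.88-fold for Rb1 and 2.02-fold for Rbm10 (exact permutation, adjusted p from 0.0028 to 0.013). A minimum of 5000 cells left no gene past the threshold, with log2 differences of 0.33 for Ambra1, 0.37 for Apc, 0.31 for Rb1 and -0.11 for Rbm10. At that minimum Ambra1 guides marked 50.4% of tumours in KTC and 14.3% in KT, pooled over mice. The log2 excess of Ambra1 number in KTC was 3.66 there, so size above this minimum does not hold the whole effect.

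**Figure D1:**
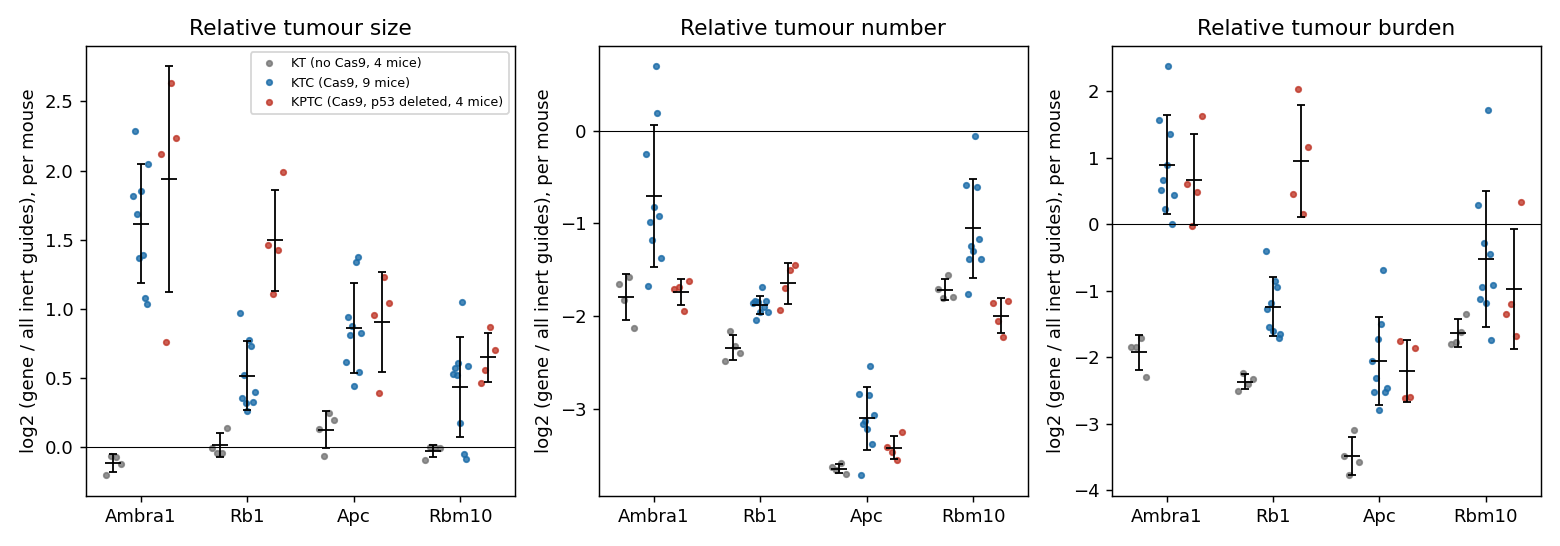
Relative tumour size (log-normal mean), number and burden of each targeted gene, as log2 of the gene over all inert guides in the same mouse. Points are mice, black bars the mean ± SD, and colours the genotypes; Ambra1 size lay above every KT mouse in 9 of 9 KTC and 4 of 4 KPTC mice, while Ambra1 number in KPTC mice (-1.74) lay near that in KT (-1.79).

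The same question was asked in mice without p53. In KPTC mice, Ambra1 tumours had a mean size of 9605 ± 5559 cells and inert tumours 2221 ± 413 cells (SD, n = 4 mice each). Relative to KT the Ambra1 tumours were 4.15-fold larger (log2 ratio 1.94 ± 0.82, SD, n = 4). Rb1 tumours were 2.80-fold larger (1.50 ± 0.36), Apc tumours 1.72-fold (0.91 ± 0.36) and Rbm10 tumours 1.60-fold (0.65 ± 0.18, SD, n = 4 each). For each of the 4 genes, 4 of 4 KPTC mice lay above every KT mouse, which gave the smallest p the 70 splits allow (exact permutation, p and adjusted p = 0.029). Leaving out any 1 KT mouse raised the adjusted p of all 4 genes to 0.057 (exact permutation). All 4 KPTC mice still lay above the KT mice left. This loss thus does not show that the increases rest on 1 KT mouse. The calls held without any 1 KPTC mouse, where as few splits were left. Fewer splits alone therefore do not explain the loss, and its cause was not tested. At a minimum of 5000 cells no gene passed: Rb1 stayed at a log2 difference of 1.58 and Ambra1 at 1.42, each at the smallest p the splits allow (exact permutation, p = 0.029, adjusted 0.057), while Apc was at 0.59 and Rbm10 at -0.0015. With number-matched tumours, the increases were 5.86-fold for Rb1, 4.32-fold for Ambra1, 2.08-fold for Apc and 1.25-fold for Rbm10 (exact permutation, adjusted p = 0.029).

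Every guide against Ambra1 enlarged tumours. In KTC mice the increase was 4.10-fold for Ambra1#1, 3.32-fold for Ambra1#2 and 2.26-fold for Ambra1#3 relative to KT (exact permutation, adjusted over 8 guides, p = 0.0037, 0.0037 and 0.025). In KPTC mice it was 6.10-fold, 3.44-fold and 2.54-fold (exact permutation, adjusted p = 0.038 each). Both Rb1 guides passed in KTC mice, at 1.37-fold and 1.39-fold. In KPTC mice Rb1#1 passed at 2.99-fold while Rb1#2 gave 2.35-fold with 3 of 4 mice above every KT mouse (exact permutation, adjusted p = 0.13). Of the Rbm10 guides, Rbm10#2 passed in KTC mice (1.47-fold) and Rbm10#1 in KPTC mice (1.67-fold). The other guide of each genotype did not pass (exact permutation, adjusted p = 0.095 for Rbm10#1 in KTC and 0.20 for Rbm10#2 in KPTC). The background was set by the 5 inert guides, each against the other 4: their size differences from KT ran from -0.10 to 0.19 on the log2 scale in KTC and from -0.06 to 0.05 in KPTC, and none passed for size, number or burden (exact permutation, smallest adjusted p = 0.14). At an unadjusted p under 0.05, 1 inert value stood out, NT1 number in KPTC at -0.17 (exact permutation, p = 0.029). That is the smallest p 4 against 4 mice allow, and adjusted over 5 guides it is 0.14. A single inert guide thus could not pass in KPTC, and the lack of a call there says little.

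**Figure D2:**
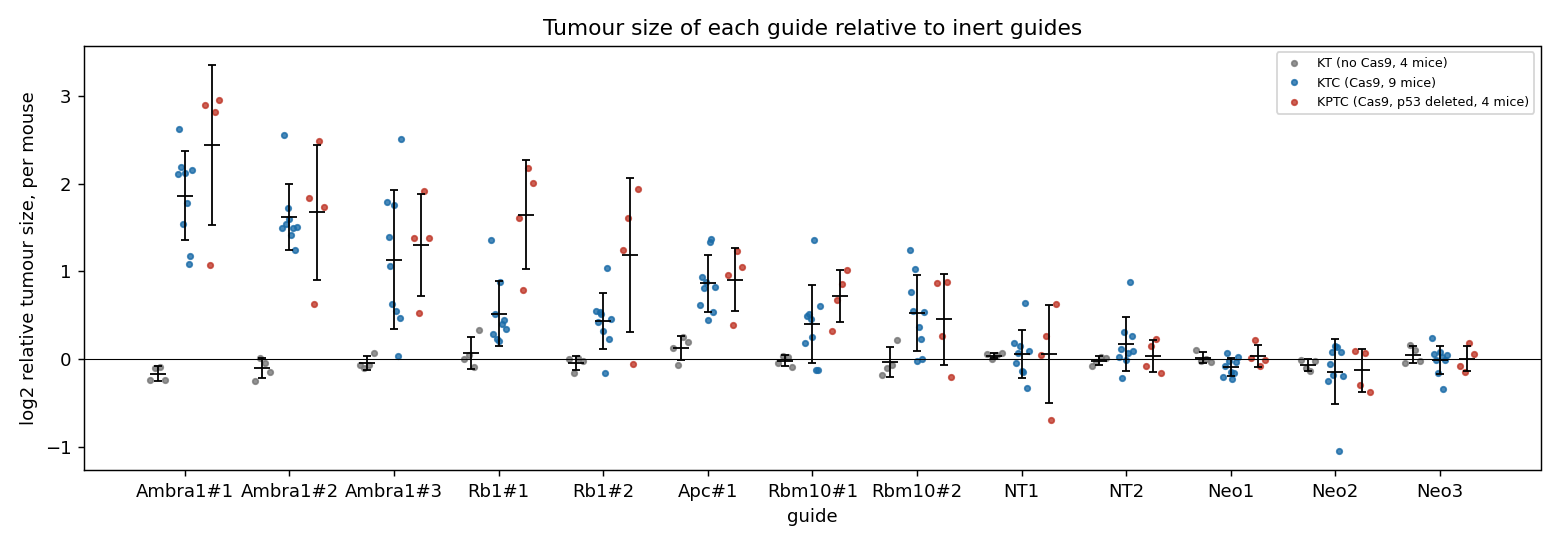
Relative tumour size of each of the 13 guides, as log2 of the guide's log-normal mean over that of all inert tumours (for an inert guide, the other inert guides) in the same mouse. Points are mice and black bars the mean ± SD; the 3 Ambra1 guides averaged 1.87, 1.62 and 1.13 in KTC mice, and the inert guides between -0.14 and 0.17.

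The enlargement by Ambra1 guides was higher at the 95th than at the 50th percentile of tumour size. In KTC mice, Ambra1 tumours were 1.96-fold larger than in KT, relative to inert tumours, at the 50th percentile, and 5.32-fold at the 95th (exact permutation, adjusted p = 0.0056 for both, n = 9 and 4). In KPTC mice the same values were 1.43-fold (exact permutation, adjusted p = 0.038) and 5.42-fold (exact permutation, adjusted p = 0.029). Rb1 tumours in KTC mice did not pass at the 50th percentile (1.05-fold, exact permutation, adjusted p = 0.36) and were 2.16-fold larger at the 95th (exact permutation, adjusted p = 0.0093). In KPTC mice the Rb1 increase went from 1.20-fold at the 50th to 4.23-fold at the 95th percentile (exact permutation, adjusted p = 0.038 and 0.029). Rbm10 in KTC mice passed at the 50th percentile (1.19-fold, exact permutation, adjusted p = 0.0056) and did not at the 95th (1.65-fold, exact permutation, adjusted p = 0.092). At the 99th percentile, Ambra1 was at 3.44-fold in KTC (exact permutation, adjusted p = 0.0056) and 5.71-fold in KPTC (exact permutation, adjusted p = 0.038), and Rb1 at 1.78-fold in KTC (exact permutation, adjusted p = 0.14) and 5.16-fold in KPTC (exact permutation, adjusted p = 0.038). Ambra1 in KPTC did not pass at the 60th, 70th or 80th percentile, at 1.81-fold, 2.65-fold and 3.89-fold (exact permutation, adjusted p = 0.15, 0.15 and 0.076). KPTC mouse 2 had log2 ratios to inert tumours of -0.13, -0.12 and -0.11 there. The other KPTC mice ran from 0.53 to 3.05 over these percentiles. No test compared one percentile with another. Percentiles were taken over tumours of at least 500 cells, close to the inert medians of single mice (617 to 1037 cells). Small tumours lifted past this minimum enter at the low end, so the lower values at the 50th percentile may in part come from the minimum.

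**Figure D3:**
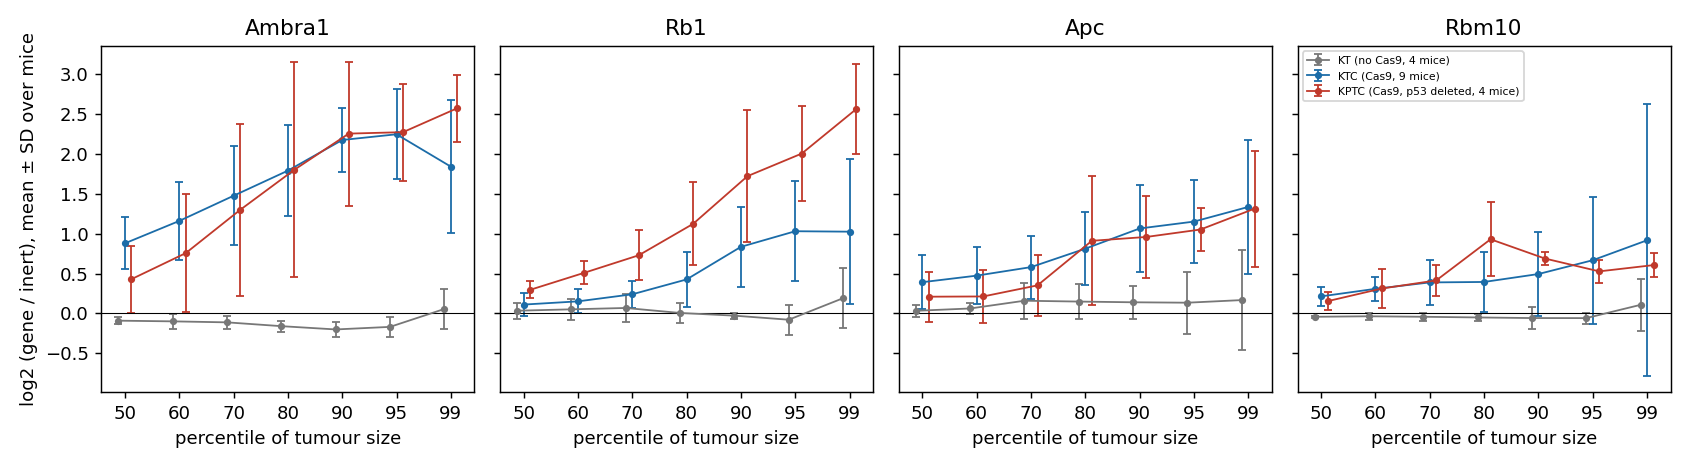
Tumour size at the 50th to 99th percentile of each gene's tumours over the same percentile of inert tumours in the same mouse, as log2 mean ± SD over mice, by genotype. For Ambra1 the KTC mean rose from 0.88 at the 50th to 2.24 at the 95th percentile, while KT values ran between -0.20 and 0.06.

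Among tumours of at least 20000 cells, Ambra1 guides had a larger share in KTC and KPTC mice than in KT mice. Of the tumours with at least 20000 cells, pooled over mice, Ambra1 guides marked 31 of 204 in KT (15.2%), 220 of 316 in KTC (69.6%) and 227 of 657 in KPTC (34.6%). Per mouse, the Ambra1 share was 12.6% ± 8.8 in KT (SD, n = 4), 60.0% ± 16.4 in KTC (SD, n = 9) and 33.4% ± 8.3 in KPTC (SD, n = 4). Rb1 guides marked 24 of 204 such tumours in KT, 27 of 316 in KTC and 164 of 657 in KPTC. The share of inert guides was 53.9% in KT, 9.49% in KTC and 24.5% in KPTC. These shares were not tested, and single mice held as few as 2 such tumours in KTC.

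**Figure D4:**
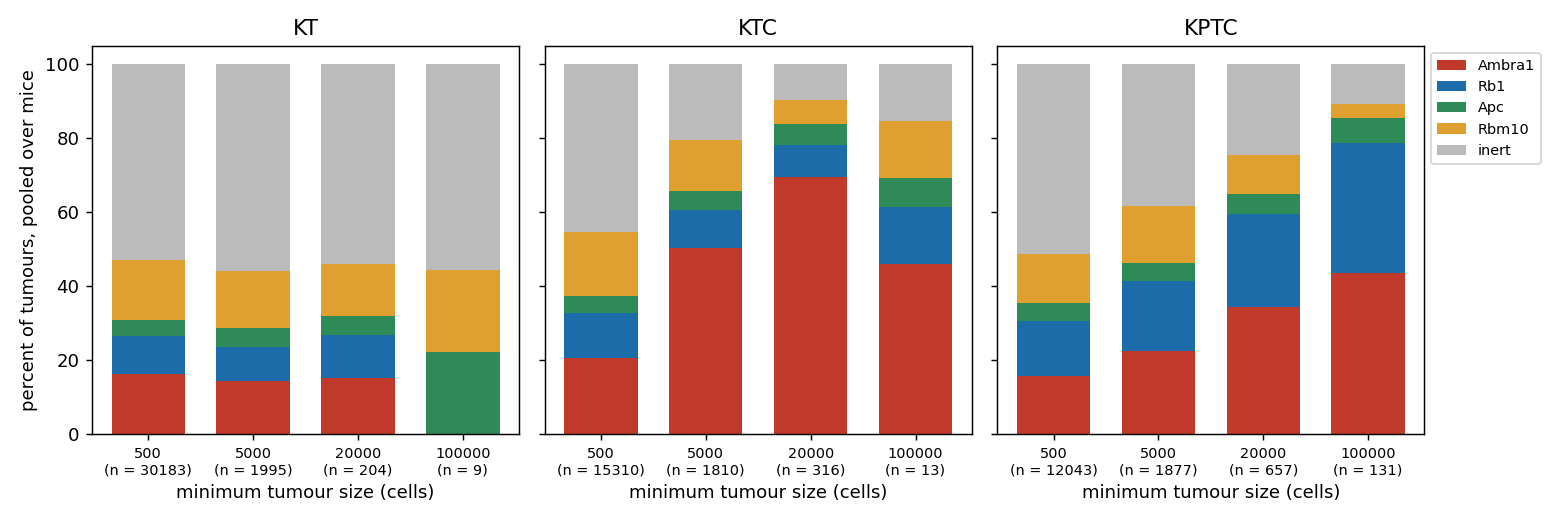
Share of each gene's guides among tumours above a minimum size (cells), pooled over the mice of a genotype; the number of tumours stands under each bar. In KTC mice the share of Ambra1 rose from 20.7% at 500 cells to 69.6% at 20000 cells, and in KT mice it stayed between 14.3% and 16.3% up to 20000 cells.

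Tumour number was compared next, to ask whether more tumours reached 500 cells. In KTC mice, tumours with each of the 4 targeted genes were more numerous relative to inert tumours than in KT mice. The excess was 2.13-fold for Ambra1 (log2 difference 1.09, 8 of 9 mice above every KT mouse), 1.58-fold for Rbm10, 1.46-fold for Apc and 1.38-fold for Rb1 (exact permutation, adjusted p = 0.028, 0.029, 0.025 and 0.0056, n = 9 and 4). Ambra1 number was uneven over KTC mice. The log2 ratio was 0.70, 0.19 and -0.25 in mice 6, 7 and 1, which had the fewest inert tumours (29, 105 and 323). It was -1.67 in mouse 2, which had the most (2622), and -1.38 to -0.82 in the other KTC mice, beside a KT mean of -1.79. Rbm10 number was also highest in mice 6, 1 and 7. Whether the excess rests on mice with few inert tumours was not tested. In KPTC mice, Ambra1 tumours gave 1.04 times the number in KT (log2 difference 0.05, exact permutation, p = 0.69), Rb1 tumours rose 1.62-fold and Apc tumours 1.17-fold, and Rbm10 tumours fell to 0.824 times (exact permutation, adjusted p = 0.038 for these 3). The Apc and Rbm10 log2 differences (0.22 and -0.28) were not far from that of inert guide NT1 (-0.17), which had the same unadjusted p. Adjusted over 8 guides, Apc#1 number did not pass (exact permutation, adjusted p = 0.057). The Ambra1 excess in KTC depended on the minimum size: it was 0.11 on the log2 scale at 200 cells (exact permutation, adjusted p = 0.62), 2.18 at 1000 cells (exact permutation, adjusted p = 0.073) and 3.66 at 5000 cells. The relative tumour number of Ambra1, KTC against KT, also lost its call without KT mouse 2 or KT mouse 4 (exact permutation, adjusted p = 0.061 and 0.068). The KTC calls of Rb1, Apc and Rbm10 ended at minimum sizes of 200 and 1000 cells. That of Apc also ended without KT mouse 2 or 4, and that of Rbm10 without any 1 KT mouse. At 1000 cells KTC mouse 6 had few inert tumours left (largest 1466 cells). The KTC SD of Ambra1 and Rb1 number was 1.68 and 1.12 there, beside 0.77 and 0.10 at 500 cells. Calls lost at 1000 cells may rest on this mouse, which was not tested. In KPTC mice, Ambra1 number moved from below KT at 200 cells (-0.36, exact permutation, adjusted p = 0.038; without KPTC mouse 1, which lists no barcode under 263 cells, -0.38, adjusted 0.076) to above it at 1000 cells (0.41, exact permutation, adjusted p = 0.076) and 5000 cells (1.59, exact permutation, adjusted p = 0.057). Rbm10 number lay above KT at 5000 cells (0.63). All 3 KPTC calls ended without any 1 KT mouse or KPTC mouse 3. With these mice left out, the KPTC values stayed on the same side of every KT value. The calls held without KPTC mouse 1, 2 or 4, where as few splits were left. Fewer splits alone therefore do not explain those losses. The calls also ended when tumours needed at least 10 reads or when inert guide NT1, Neo1 or Neo2 was left out. Over all listed barcodes, whose smallest size ran from 2.15 to 40.7 cells in KT mice and from 7.43 to 263 cells in KPTC mice, the KPTC values were close to those at 500 cells for Apc (1.12-fold, 4 of 4 mice above every KT mouse) and Rbm10 (0.803 times, 4 of 4 below), and lower for Rb1 (1.05-fold, exact permutation, adjusted p = 0.057, 0.057 and 0.46). The lower Rbm10 number in KPTC was thus not particular to tumours of at least 500 cells.

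Tumour burden combined size and number. Ambra1 guides carried 7.07-fold more neoplastic cells relative to inert guides in KTC than in KT mice (log2 difference 2.82, 9 of 9 mice, exact permutation, adjusted p = 0.0028), and Apc, Rb1 and Rbm10 guides 2.68-fold, 2.18-fold and 2.17-fold more (exact permutation, adjusted p = 0.0037, 0.0028 and 0.048). In KPTC mice, Rb1 guides had the highest increase, 9.96-fold, followed by Ambra1 at 6.06-fold and Apc at 2.42-fold (exact permutation, adjusted p = 0.038 each, n = 4 and 4), and Rbm10 did not pass (1.58-fold, exact permutation, p = 0.14). The Rbm10 call in KTC ended in 9 of the 13 settings that left out 1 KTC or KT mouse (exact permutation, adjusted p up to 0.10). A single Rb1#1 tumour of 20568200 cells made up 43.9% of all tumour cells in KPTC mouse 2, and without the largest tumour of each gene and mouse the Rb1 log2 difference in KPTC was 2.70 instead of 3.32.

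The effects were then compared between KTC and KPTC mice, which asks whether they depended on p53. Rb1 differed most in size and burden, and least in number. Its tumours were larger relative to inert ones in KPTC (log2 ratio 1.50 ± 0.36, SD, n = 4) than in KTC (0.52 ± 0.25, SD, n = 9), with all 9 KTC mice below every KPTC mouse (difference -0.98, exact permutation, adjusted p = 0.0056). Rb1 burden differed by -2.19 (exact permutation, adjusted p = 0.0056) and Rb1 number by -0.23 (exact permutation, adjusted p = 0.028). Ambra1 number was 2.05-fold higher in KTC than in KPTC, and Rbm10 number 1.92-fold higher (exact permutation, adjusted p = 0.028 each). In KTC both numbers were highest in mice 1, 6 and 7, which had the fewest inert tumours. For Ambra1 size the difference was -0.32 (exact permutation, p = 0.36), and for Ambra1 burden 0.22 (exact permutation, p = 0.63).

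The relative tumour size of Ambra1, KTC minus KPTC, had no settled direction: it was 0.62 with number-matched tumours (exact permutation, p = 0.12), -1.09 at a minimum of 5000 cells (exact permutation, adjusted p = 0.0081) and -0.71 without KPTC mouse 2 (exact permutation, adjusted p = 0.045). The call on Ambra1 number ended without KTC mouse 1 or any 1 KPTC mouse (exact permutation, adjusted p 0.054 to 0.097), that on Rb1 number without KTC mouse 1 or KPTC mouse 2, 3 or 4, and that on Rbm10 number without KPTC mouse 3. By minimum size, the Rb1 number call held at 500 cells alone (-0.098 at 200, 0.018 at 1000 and -0.11 at 5000 cells, exact permutation, p = 0.30, 0.996 and 0.82), and the Rbm10 number call ended at 1000 and 5000 cells (1.34 and 0.59, exact permutation, p = 0.078 and 0.21). At 1000 cells KTC mouse 6 had few inert tumours left (largest 1466 cells), and the KTC SD of Rb1 number was 1.12, beside 0.10 at 500 cells. Number calls lost at 1000 cells may rest on this mouse, which was not tested. All KPTC mice were male.

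Ambra1 was also ranked against the other genes within each mouse by exact sign-flip tests. In KTC mice, Ambra1 tumours were 2.14-fold larger than Rb1 tumours and 2.27-fold larger than Rbm10 tumours in 9 of 9 mice (exact sign-flip, adjusted p = 0.0059 each). They were 1.69-fold larger than Apc tumours in 8 of 9 mice (exact sign-flip, adjusted p = 0.012), each relative to inert tumours. In KPTC mice they were 1.36-fold larger than Rb1 tumours in 3 of 4 mice, and 2.04-fold and 2.44-fold larger than Apc and Rbm10 tumours in 4 of 4 mice, where 4 mice cannot give an exact p below 0.125. At a minimum of 5000 cells the KTC differences were 0.09 for Rb1, -0.13 for Apc and 0.27 for Rbm10, none past the threshold. The Apc call also ended at 1000 cells, in male mice alone and with barcodes listed in 1 mouse only. In KPTC mice the Rb1 difference turned to -0.55 with number-matched tumours.

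Inert tumours showed how the genotypes differed without a targeted gene. They were larger in KPTC than in KTC mice, with geometric means over mice of 2193 cells (n = 4) and 1306 cells (n = 9), a 1.68-fold difference (exact permutation, adjusted over 3 comparisons, p = 0.021). The geometric mean in KT mice was 1579 cells (n = 4). The 95th percentile of inert tumours was 11556 cells in KPTC, 2.95-fold higher than in KTC and 2.11-fold higher than in KT (exact permutation, adjusted p = 0.029 and 0.043). Size did not pass between KTC and KT (0.827 times, exact permutation, p = 0.26) or between KPTC and KT (1.39-fold, exact permutation, adjusted p = 0.086). Inert tumours numbered 771 ± 777 per mouse in KTC (SD, n = 9), 1544 ± 1269 in KPTC and 3985 ± 2440 in KT (SD, n = 4 each). Listed barcodes of all sizes and guides also differed, with means of 57916 in KTC, 23673 in KPTC and 175727 in KT, so tumour counts per mouse do not separate genotype from the number of cells infected or of barcodes listed. The difference in inert tumour number between KTC and KT did not pass (exact permutation, adjusted p = 0.055). The size difference between KPTC and KTC lost its call without KPTC mouse 2 or 3 (exact permutation, adjusted p = 0.055 and 0.095) and at minimum sizes of 200 and 5000 cells, and that of the 95th percentile against KT without KPTC mouse 3 or any 1 KT mouse (exact permutation, adjusted p = 0.086). At the 95th percentile every KPTC mouse lay above every KT mouse (lowest KPTC value 8016, highest KT value 7296 cells). The call against KT held without KPTC mouse 1, 2 or 4, where as few splits were left. Fewer splits alone therefore do not explain its losses. The 95th percentile against KTC lost its call without KPTC mouse 3 (exact permutation, adjusted p = 0.086), and both 95th percentile calls ended at minimum sizes of 200 and 5000 cells.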

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

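The tests of the virus share and of a uniform shift by number-matched size, and the settings with male mice only, with at least 10 reads, with KPTC mice 1 and 2 or 3 and 4 only and without KPTC mouse 1 at 200 cells or over all barcodes, were chosen only after results were seen. A search of 45 groups of values for a single mouse far from the others found 3, where chance flags about 1 in 20 groups.

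KTC mouse 6 stood apart from the other 8 KTC mice in its inert tumours. Their log2 log-normal mean size was 9.38 beside 10.13 to 10.73, and their log2 95th percentile 9.82 beside 11.28 to 12.73. This mouse had 29 inert tumours of at least 500 cells. The largest had 1466 cells, so few were left at a minimum of 1000 cells, and number calls lost there may rest on this mouse. Rbm10 tumours of KT mouse 1 had a log2 relative size of -0.092, beside -0.0089 to -0.0016 in the other 3 KT mice. Between KTC and KPTC mice, 5 differences passed the exact permutation test: Rb1 size (-0.98), Rb1 number (-0.23), Rb1 burden (-2.19), Ambra1 number (1.04) and Rbm10 number (0.94). The Rb1 number call held at a minimum of 500 cells alone (p = 0.30, 0.996 and 0.82 by exact permutation at 200, 1000 and 5000 cells), and the Rbm10 number call ended at 1000 and 5000 cells (exact permutation, p = 0.078 and 0.21).

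Ambra1 tumours of at least 500 cells were more numerous relative to KT in KTC than in KPTC mice, by 1.04, and the difference was 0.47 at a minimum of 200 cells (0.49 without KPTC mouse 1, which lists none under 263 cells), 1.77 at 1000 (adjusted exact permutation p = 0.16) and 2.08 at 5000. Growth of every Ambra1 tumour by its mouse's number-matched size factor predicts an excess over KT of 3.87 in KTC and 2.24 in KPTC. The observed excess differed from this by -2.77 (SE 0.32) and -2.18 (SE 0.60), which argues against a uniform shift within each genotype. The size factor above 500 cells understates a uniform shift and so predicts too low an excess. The observed excess still lay below it (-1.39, SE 0.15, and -2.14, SE 0.38). These tests cannot decide the difference between genotypes, since the predicted excess was itself higher in KTC. In the simulation, an equal 4-fold enlargement of every barcode also gave a higher number in KTC (2.82) than in KPTC (2.18). KPTC mouse 1 lists no barcode under 263 cells, so neither the simulation nor the prediction could lift smaller tumours there. This lowers both KPTC values, by an amount that was not tested. The measured number at 500 cells has no such gap. Whether a fixed minimum alone can give such a difference at an equal effect thus stays open. The difference between genotypes was 1.39 in male mice (exact permutation, p = 0.029, adjusted 0.057) and 0.97 with at least 10 reads (exact permutation, p = 0.029). Over all listed barcodes it was 0.059 (exact permutation, p = 0.44), and 0.098 without KPTC mouse 1. These values argue against sex, few reads and an unequal share of virus as its whole source. The filter of 10 reads acted on KPTC mouse 1 alone (3.80 reads at 500 cells) and gave it a higher minimum size than the other mice. The call ended without KTC mouse 1 (0.98) or any 1 KPTC mouse (0.97 to 1.08), with an adjusted exact permutation p of 0.054 to 0.097. As a hypothesis, p53 status may change how many Ambra1 tumours reach a given size; this was not tested, since it needs littermates that differ in p53 alone, and uneven growth among tumours and other differences between the cohorts stay open.

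Rb1 tumours were larger relative to inert tumours in KPTC than in KTC mice. With at least 10 reads per tumour, which changed KPTC mouse 1 alone, the difference was -1.06 (exact permutation, p = 0.0014). In male mice the difference was -0.94 (exact permutation, p = 0.029, adjusted 0.11). These values argue against few reads or sex as the whole source of the difference. It was -1.64 with number-matched tumours (exact permutation, adjusted p = 0.0056), -0.36 with the geometric mean (exact permutation, adjusted p = 0.011), and lost its call with the 95th percentile as size (-0.97, exact permutation, adjusted p = 0.10). As a hypothesis, loss of p53 may enlarge the effect of Rb1 guides; this was not tested either, for want of such littermates, and other differences between the cohorts stay open.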

How the results depend on the processing

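Male mice only, barcodes listed in 1 mouse only, at least 10 reads, KPTC mice 1 and 2 or 3 and 4 only and permutation within sex, as well as leaving out KPTC mouse 1 at 200 cells, were chosen after results were seen. All differences are log2 values. Leaving out barcodes 1 mismatch from a larger one removed 0 barcodes and so tested nothing. Rescaling from the benchmark lines was not run, since their reads were not used here. No paired analysis was possible because each mouse has a single genotype and the labels pair no mice. Male mice against KT and 2 KPTC mice against KT (smallest p 0.067), and sign-flips over 4 mice (smallest p 0.125), could not reach the threshold, so calls lost there say nothing about stability. For the other changes the cause was not tested. Reads limit small tumours most in KPTC mouse 1, where 500 cells are 3.80 reads.

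A minimum of 200 cells could not be applied in KPTC mouse 1, which lists no barcode under 263 cells. At 200 cells, Ambra1 number was 0.11 in KTC and -0.36 in KPTC (-0.38 without that mouse), and 0 genes passed for number in KTC. KTC minus KPTC was then 0.25 for Ambra1 size, 0.080 for Apc size, 0.14 for Rbm10 size, -0.16 for Ambra1 burden and -0.12 for Apc burden, and inert size of KPTC against KTC was 0.47. At 1000 cells, Ambra1 number in KTC was 2.18, and 0 genes passed for number in either genotype. KTC mouse 6, whose inert tumours had a 95th percentile of 905 cells and a maximum of 1466, had few left at this minimum. The KTC SD of Ambra1 number was 1.68 there, beside 0.77 at 500 cells and 0.83 at 5000 cells, where this mouse gave no value. For Rb1 number the SD was 1.12, beside 0.10 and 0.62. Calls lost at 1000 cells may thus rest on this mouse. KTC minus KPTC was then 1.77 for Ambra1 number, -0.77 for Ambra1 size (past the threshold) and 0.018 for Rb1 number. Inert size of KPTC against KT was 0.80 (past the threshold), and Ambra1 minus Apc in KTC was 0.45. At 5000 cells, where KTC mouse 6 gave no value, size was 0.33 for Ambra1 and -0.11 for Rbm10 in KTC, and 1.42 and -0.0015 in KPTC. There 0 genes passed for size in either genotype or for number in KPTC, where Rbm10 number was 0.63. Ambra1 size in KTC minus KPTC was -1.09 (past the threshold), and inert size was 0.63 for KPTC against KTC and 0.15 for KTC against KT. Ambra1 minus Apc, Rb1 and Rbm10 in KTC was -0.13, 0.091 and 0.27, and Ambra1 minus Rb1 in KPTC was -0.094.

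With other measures of size, KTC minus KPTC for Ambra1 was 0.18 with the geometric mean and 0.62 with number-matched tumours. For Apc it was 0.13 with the geometric mean, 0.099 with the 95th percentile and 0.23 with number-matched tumours, and for Rbm10 it was 0.14 and 0.70 with the latter 2. Ambra1 minus Rb1 in KPTC was -0.55 with number-matched tumours. With tumours pooled over mice, Ambra1 size against KT was 1.91 in KTC (bootstrap 95% interval 1.53 to 2.18) and 1.80 in KPTC (0.95 to 2.60). Sign-flips left Ambra1 size in KPTC at 1.94 relative to inert tumours, with 0 genes past the threshold for size or number. For number in KPTC, 0 genes passed with at least 10 reads, with barcodes in 1 mouse only, with shared barcodes kept where largest, or without NT1, Neo1 or Neo2. Barcodes in 1 mouse only gave 0.24 for Ambra1 minus Apc in KTC, -0.057 for Ambra1 burden in KTC minus KPTC, and 0.47 for inert size of KPTC against KT (past the threshold).

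In male mice, Ambra1 had size 1.45, number 1.35 and burden 2.82 in KTC, and 2.00, -0.040 and 2.45 in KPTC, with 0 genes past the threshold. KTC minus KPTC was 1.39 for Ambra1 number and 0.11 for Apc size, and inert size of KPTC against KTC was 0.93. Ambra1 minus Apc, Rb1 and Rbm10 in KTC was 0.37, 0.83 and 1.01. With KPTC mice 1 and 2 only, Ambra1 size and burden were 1.56 and 2.22. The relative tumour number of Ambra1, KTC minus KPTC, was then 0.997, the same difference was 0.18 for Ambra1 size and 0.19 for Apc size, and inert size against KTC was 0.73. With mice 3 and 4 only, Ambra1 size was 2.55, and the relative tumour burden of Ambra1, KPTC against KT, was 2.98. KTC minus KPTC was then 1.08 for Ambra1 number and -0.16 for Ambra1 burden, and inert size against KTC was 0.77. With either pair, 0 genes passed against KT for size, number or burden.

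With 1 mouse left out at a time, Ambra1 size in KTC ran from 1.65 to 1.80 and burden from 2.64 to 2.93, and both passed in each of the 13 settings that left out a KTC or KT mouse. Ambra1 size in KPTC ran from 1.82 to 2.44, and its call ended without any 1 KT mouse. Every KPTC mouse still lay above the KT mice left. The call held without any 1 KPTC mouse, where as few splits were left, so fewer splits alone do not explain that loss. Ambra1 number ran from 0.92 to 1.21 in KTC, where its call ended without KT mouse 2 or 4, and from -0.056 (without KT mouse 4) to 0.13 in KPTC. KTC minus KPTC ran from 0.86 to 1.16 for Ambra1 number, where the call ended without KTC mouse 1 or any 1 KPTC mouse. It ran from -0.71 (without KPTC mouse 2, past the threshold) to -0.088 for Ambra1 size, and from -0.0095 (without KPTC mouse 2) to 0.54 for Ambra1 burden. Apc size ran from -0.22 to 0.066, above 0 without KTC mouse 5 or KPTC mouse 3 or 4, and Apc burden from -0.027 (without KTC mouse 7) to 0.30. Inert size ran from 0.36 to 0.57 for KPTC against KT (past the threshold without KPTC mouse 4), and from 0.63 to 0.84 against KTC (call lost without KPTC mouse 2 or 3). Genes past the threshold numbered 0 to 4 for size and 0 to 3 for number in KPTC, and 1 to 4 for number in KTC. Under all alternatives except those that left out 1 mouse, and so with male mice only, KPTC pairs and sign-flips included, the values of Apc, Rb1 and Rbm10 and of inert number and 95th percentile kept direction and side of the threshold in 277 cases (the setting that removed 0 barcodes not counted), lost their call in 113, gained one in 2 and changed sign in 14. The 113 thus include losses in settings that could not reach the threshold.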

Other observations

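The test of barcode collisions in KT mice and the setting with barcodes in 1 mouse only were chosen only after results were seen.

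The 7 tumours of at least 1000000 cells were all in KPTC mice. Of these, 5 carried Rb1 guides, all in KPTC mice 1 and 2, 1 carried an Ambra1 guide and 1 an Rbm10 guide. Tumours of at least 100000 cells numbered 9 in KT, 13 in KTC and 131 in KPTC mice, of which Ambra1 guides marked 0, 6 and 57 and Rb1 guides 0, 2 and 46.

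When all listed barcodes were counted, down to 2 reads or 2.15 to 40.7 cells in KT and 3.78 to 17.8 cells in KTC mice, Rbm10 barcodes were rarer relative to inert barcodes in KTC than in KT mice (log2 difference -0.29, below every KT mouse in 9 of 9, exact permutation, adjusted p = 0.0056). The value in KPTC was -0.32 (4 of 4 mice, exact permutation, adjusted p = 0.057). The KT ratio, used as baseline for number and number-matched size, thus did not hold for Rbm10 over all listed barcodes. The smallest listed size also differed between mice. The same count for Ambra1 was -0.15 in KTC (exact permutation, adjusted p = 0.062). In KT mice, Ambra1 tumours were smaller than inert tumours in 4 of 4 mice (exact sign-flip, p = 0.125, the smallest that 4 mice allow). Female KTC mice had a geometric mean of 891 inert tumours and males 180, a 4.95-fold difference that did not pass (exact permutation, p = 0.079, adjusted 0.24, n = 5 and 4).

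Barcodes of the Ambra1 guides were less diverse than those of most guides. For Ambra1#1, #2 and #3, 81.1%, 74.9% and 52.8% of barcodes occurred in more than 1 mouse, beside 52.3% for Apc#1, 40.9% for NT2 and 7.24% to 19.9% for the others. Separate tumours of a mouse that share a barcode could look like 1 larger tumour. Over the 3 guides, the expected share of such Ambra1 barcodes was at most 10.1% in a mouse with Cas9 and 17.0% to 25.8% in KT mice (by guide at most 12.5%, 11.1% and 5.30% with Cas9, and 21.1% to 32.1%, 18.8% to 28.0% and 8.39% to 13.6% in KT), where Ambra1 tumours nevertheless had a log2 relative size of -0.11 ± 0.07 (SD, n = 4). With barcodes listed in 1 mouse only, which kept 2552 of the 9975 Ambra1 tumours of all mice, the KTC difference from KT was 1.37. This was 79.3% of its value with all barcodes (exact permutation, p = 0.0028). These values argue against shared barcodes as the whole source of the larger Ambra1 tumours, and loss of Ambra1 stays a hypothesis, since no deposited value measures it.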
